A study of Homo sapiens with 8 samples.

How the data were processed

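Poly(A) RNA of NB4 and MM6 cells was sequenced in 8 libraries, 2 for each of 4 groups: NB4 and MM6, each with the METTL14 hairpin shM14 (labelled shM14-#2) or with the non-specific hairpin shNS. Per the labels, cells were transduced with lentiviral pLKO.1 hairpins, kept in 0.5 µg/mL puromycin for 2 passages and lysed in TRIzol. Libraries were made from 100 ng of total RNA with a directional kit, and single-end reads of 50 bp were obtained. The aligner, the read counter, the genome build and the test behind the authors' p-values are not given in the sources used here. The strand on which reads were counted is not stated either, so values of overlapping or antisense genes and of close paralogs are less certain. The values do not come with genome coordinates, and genes are named by the symbol the files pair with each gene ID; 27 of the 16726 genes have no symbol.

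The authors deposited 1 table per cell line with 5 kinds of values. The RPKM values of each library are, as deposited, reads per kilobase of gene model and 1e6 reads assigned to genes; this unit was worked out from the values because the headers do not name it. The signal columns hold group means of reads divided by a size factor per library, computed by the authors. The ratio column is the authors' fold change of shM14 over shNS, finite even where a group is at 0. The log2 column is, per the file headers, the log2 of that fold change. The p-value columns are the authors' p and its Benjamini-Hochberg adjustment over all 16726 rows, which was checked by recomputing it. RPKM and group means together resolved into whole reads for 100% of the values within a tolerance of 0.01, and the same recovery was tested on 4000 simulated genes. The recovered reads gave the depth of each library over the listed genes. The listed genes held 99.98% of the RPKM total in each library.

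Because the deposited values hold no read counts as such, the planned count models were not used. Those models fitted all 8 libraries together, also for the change within each line. For values such as RPKM the plan named limma within each line. Genes with an RPKM of at least 1 in at least 2 libraries were kept, and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a Benjamini-Hochberg threshold of 0.05. Each line was fitted alone, 2 libraries against 2. The effect common to both lines came from an additive model of cell line and hairpin over all 8 libraries. The difference between lines was the interaction, MM6 change minus NB4 change, over all 8 libraries. A log2 change on this scale understates the change of genes with a low RPKM. Changes are shM14 minus shNS throughout, and SE is the moderated standard error. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

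The 31 gene lists, the models and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; 24 lists were tested in NB4, 23 in MM6 and 26 in the fits over both lines. Smaller lists are described by their members. The alternative with an estimated correlation also tests each list on the residual degrees of freedom of the fit. These were 2 in each line, 5 in the common fit and 4 in the difference, so few lists could pass there whatever their correlation. The list of MYB, MYC and SPI1 was taken from what the study reported, so its values are not independent evidence. Members called after adjustment over the list alone are counted beside those adjusted over all genes.

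Genes are named by a fixed rule. In each line these are METTL14, the m6A list, MYB, MYC and SPI1. They also include the 10 genes with the largest change up and the 10 down among those past the threshold. Such a gene needs a mean of at least 5 CPM in its higher group (from recovered reads), no overlap between the groups, and a symbol that is not a placeholder. For both lines together the rule ranks genes past the threshold in both by the smaller of their changes, without a minimum of reads. Since MM6 had few calls, the same ranking was also applied to genes past the threshold of the common fit, which was chosen after the values were seen. For the difference between lines the rule takes the 5 genes with the smallest p in each direction, and for each list up to 4 members with the smallest p. Some genes that met these rules are not reported here.

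The alternatives chosen beforehand that could be run were a pseudocount of 0.1, no filter, a filter of 10 CPM in 2 libraries, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library. The alternatives added after the values were seen were all 8 libraries in 1 model for each line, with and without the block, a variance trend, voom on the recovered reads, voom with all 8 libraries, and median-of-ratios scaling. A single model of all 8 libraries had been planned for counts, but not for RPKM values. The lines share no control libraries.

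The fits were tested on simulated data made from these libraries, with 200 changed genes. In NB4, 87.9%, 96.4% and 98.2% of genes changed by 1.5, 2 and 4 fold were called. In MM6 the shares were 3.51%, 67.9% and 98.2%, and in the common fit 79.3%, 95.2% and 100%. Of the calls, 5.53%, 5.79% and 1.60% were unchanged genes. For genes changed in NB4 alone, the difference test called 6.90%, 59.5% and 89.7% at these folds, with 3.64% unchanged genes among the calls. A simulated list shifted by 1.4 fold was called in NB4, MM6 and the common fit, with 0 other lists called. The simulated genes were drawn independently of each other, whereas in MM6 the estimated correlation of the interferon list was 0.69. The simulation therefore does not show how often unchanged lists of correlated genes are called. The spread of the most variable genes was also capped and drawn towards the median, and no shift shared by libraries was simulated. The shares of changed genes called may therefore be too high for the real libraries, above all in MM6.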

Results

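The data were RNA sequencing libraries of NB4 and MM6 (MonoMac 6), both established human acute myeloid leukaemia lines. NB4 is known as a promyelocytic line that can be driven to mature, and MM6 as a monocytic one, although the labels give acute monocytic leukemia for both. Each line carried a lentiviral hairpin against METTL14 (shM14) or a non-specific control hairpin (shNS), with 2 libraries in each of 4 groups. METTL14 is the partner of the methyltransferase METTL3 in the complex that writes N6-methyladenosine (m6A) on RNA. The question was which transcripts change in leukaemia cells when METTL14 is lowered. Depth was 23272126 to 28814911 reads per library over 16726 listed genes, of which 16185 to 16403 had a read. The 10 most abundant genes held 4.80% to 7.07% of the reads, led by EEF1A1 or, in 2 MM6 libraries, LYZ. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries.

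METTL14 (gene 57721) was lower in each of the 4 knockdown libraries than in each of the controls of its line. In NB4 it went from 13.3 ± 1.12 to 8.35 ± 0.00266 RPKM (SD, n = 2 each), a change of -37.1% and of -0.61 in log2 (SE 0.07, adjusted p = 0.0024). In MM6 it went from 12.9 ± 0.599 to 6.54 ± 0.00383 RPKM (SD, n = 2 each), a change of -49.4% and of -0.88 in log2 (SE 0.13, adjusted p = 0.088). This did not pass the threshold in MM6 alone. With the replicate number as a block it did (adjusted p = 0.0089), though the labels state no pairing. Over both lines the change was -0.75 (adjusted p = 0.0032), and the lines were not shown to differ (difference -0.28, adjusted p = 0.27). In the authors' deposited table the log2 fold changes of METTL14 were -0.64 in NB4 (adjusted p = 1.7e-16) and -0.94 in MM6 (adjusted p = 0.0049). The partner METTL3 had changes of 0.05 and 0.24 and passed in neither line. WTAP, the scaffold of the writer complex, rose in NB4 by 0.28 and over both lines by 0.30, and the m6A reader IGF2BP3 rose by 0.58 and 0.51. The eraser ALKBH5 rose by 0.15 in NB4 only just past the threshold (adjusted p = 0.049). As a group, the 22 writers, erasers and readers did not move: in NB4 3 were higher, 1 lower and 18 not passed, with 2 and 1 when adjusted over the list alone (list adjusted p = 0.34). In MM6 none of 21 passed over all genes and METTL14 passed adjusted over the list alone (list adjusted p = 0.91).

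MYB and MYC encode transcription factors that maintain leukaemic and progenitor growth, and SPI1 (PU.1) encodes a master regulator of monocytic maturation. The study named MYB and MYC as METTL14 targets and SPI1 as its regulator, so these 3 are not independent evidence. In NB4, MYC fell from 252 ± 5.11 to 173 ± 0.874 RPKM (SD, n = 2 each), a log2 change of -0.54 (adjusted p = 0.0013), and SPI1 rose from 48.2 to 57.6 RPKM (0.25, adjusted p = 0.025). MYB had 59.6 and 65.8 RPKM in NB4 (0.14, adjusted p = 0.069). In MM6, MYB had 118 ± 22.3 RPKM in controls and 77.5 ± 27.1 with shM14 (SD, n = 2 each; -0.63, adjusted p = 0.37). MYC had 93.9 and 70.9 RPKM (-0.56, adjusted p = 0.71) and SPI1 105 and 148 RPKM (0.48, adjusted p = 0.25) in MM6. MYC in MM6 was uneven, with changes of -1.01 and -0.11 between libraries of the same number. Over both lines SPI1 rose by 0.37 (adjusted p = 0.037), whereas MYC (-0.55, adjusted p = 0.26) and MYB (-0.25, adjusted p = 0.46) did not pass. Adjusted over the list alone, MYC fell and MYB and SPI1 rose in NB4, and no member passed in MM6.

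**Figure D1:**
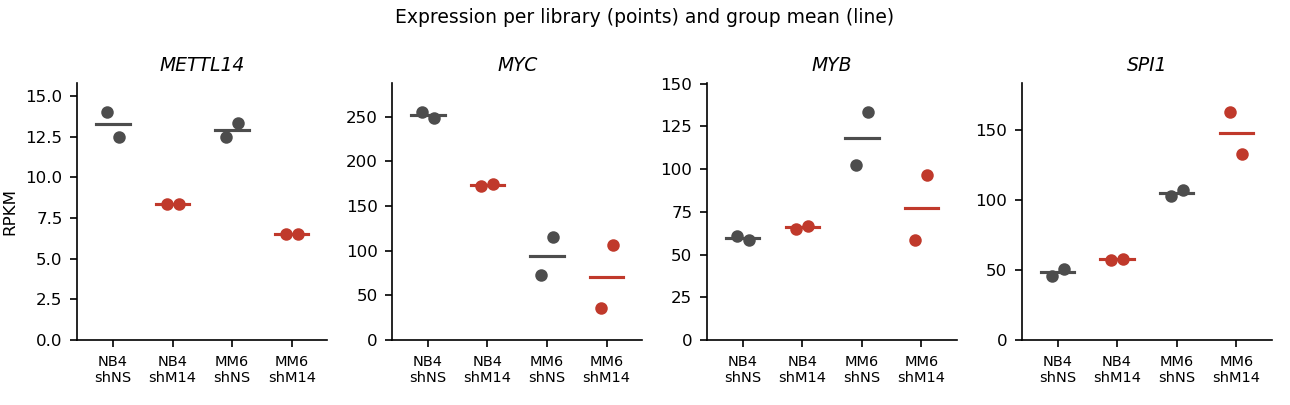
RPKM of METTL14, MYC, MYB and SPI1 in the 8 libraries (points, grey for shNS and red for shM14) with the group mean (line), for NB4 and MM6. METTL14 means went from 13.3 to 8.35 RPKM in NB4 and from 12.9 to 6.54 RPKM in MM6, without overlap between groups.

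In NB4, lowering METTL14 was accompanied by the rise of genes of monocytes and of inflammation and by the loss of interferon-response genes and of a granule protease. THBS1, which encodes the adhesive glycoprotein thrombospondin 1, rose from 3.47 ± 0.220 to 63.1 ± 0.565 RPKM (SD, n = 2 each), a log2 change of 3.84. The cytokine gene IL1B rose by 3.11, the growth factor gene HGF by 2.76, and the chemoattractant receptor C5AR1 by 2.42. The adhesion molecule ICAM1 (2.18), the kinase SGK1 (2.17), the sulfotransferase CHST2 (2.16), the transcription factor OLIG1 (2.12), the chemokine CCL4 (2.12) and the scavenger receptor CD36 (2.07) also rose. CTSG, the neutrophil serine protease cathepsin G, fell from 43.4 ± 2.14 to 6.79 ± 0.0829 RPKM (SD, n = 2 each), a change of -2.51. The interferon-induced genes IFI27 (-2.58), IFI44 (-2.51), OAS2 (-2.36), OAS3 (-2.34), MX1 (-2.09) and IFIT2 (-2.04) fell. So did LGALS3BP (-2.17), a secreted glycoprotein, the imprinted RNA H19 (-1.94) and the matrix protein gene MFAP4 (-1.79). These 20 genes had adjusted p of 8.6e-05 to 2.4e-04. Passing the threshold without overlap between groups was a condition for naming them. In all, 2553 genes were higher and 2907 lower among 11531 tested, of which 91 and 104 changed by at least 2 fold. The balance depended on scaling: with median-of-ratios scaling 2922 were higher and 2600 lower. Most were small changes, with a median size of 0.33 in log2. Under the threshold in the authors' deposited table were 7293 genes of NB4, and 5236 of the 5460 genes called here were among them with the same direction.

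The interferon response was the most uniform group in NB4. Of 38 tested members 36 fell, 0 rose and 2 did not pass, with a median change of -1.36, and the list ranked below other genes (adjusted p = 1.3e-20, and 0.21 with an estimated correlation); 36 fell when adjusted over the list alone. Monocyte and macrophage genes rose: 20 of 26 were higher, 2 lower and 4 not passed (median 0.49, adjusted p = 1.8e-07, and 0.21 with an estimated correlation), again 20 and 2 when adjusted over the list alone. Among them, LYZ, which encodes lysozyme, rose from 20.6 to 84.0 RPKM. NF-kB and inflammatory genes rose in 18 of 25 and fell in 1, as they did adjusted over the list alone (median 0.63, adjusted p = 1.8e-07, and 0.21 with an estimated correlation), with the chemokine CCL2 at 2.04 and IER3 at 1.51. Messenger RNAs of cytosolic ribosomal proteins fell in 30 of 46, with 0 higher and 34 lower adjusted over the list alone. Their median was -0.23 (adjusted p = 1.8e-07, and 0.36 with an estimated correlation). RPLP1, a protein of the ribosomal stalk, led them at -0.86. Oxidative phosphorylation genes rose in 18 of 30 and fell in 1, 19 and 1 over the list alone (median 0.23, adjusted p = 3.3e-05, and 0.27 with an estimated correlation), with COX7B at 0.55. Lysosome and autophagy genes rose in 17 of 30 and fell in 4, equally over the list alone (median 0.22, adjusted p = 3.7e-04, and 0.28 with an estimated correlation), with CTSA at 1.16 and LAMP1 at 0.89.

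Further NB4 lists called concerned stress, growth and lipid genes. Integrated stress and unfolded protein response genes rose in 16 of 29 and fell in 4, as over the list alone (median 0.21, adjusted p = 7.6e-04, and 0.28 with an estimated correlation), led by the endoplasmic reticulum protein PDIA4 at 0.94. Immediate early genes rose in 14 of 25 and fell in 2, with 15 and 2 adjusted over the list alone (median 0.22, adjusted p = 0.0014, and 0.36 with an estimated correlation); DUSP2 rose by 1.04 and SPRY2 fell by 0.48. Cholesterol synthesis genes rose in 15 of 24 and fell in 4, with 15 and 5 adjusted over the list alone (median 0.21, adjusted p = 0.011, and 0.30 with an estimated correlation), led by INSIG1 at 0.87. Heat shock genes rose in 10 of 15 and fell in 2, with 11 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.015, and 0.30 with an estimated correlation), HSPA4 at 0.34. Mitosis genes rose in 12 of 30 and fell in 1, equally over the list alone (median 0.09, adjusted p = 0.016, and 0.31 with an estimated correlation), with CENPA and MKI67 both at 0.48. MYC target genes rose in 12 of 30 and fell in 5 although MYC itself fell; over the list alone 15 and 5 passed (median 0.13, adjusted p = 0.021, and 0.37 with an estimated correlation). The transferrin receptor TFRC rose by 0.88 and TERT, the telomerase subunit, fell by 0.67. Ribosome biogenesis genes rose in 9 of 29 and fell in 1, with 7 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.035, and 0.33 with an estimated correlation); TCOF1 rose by 0.40 and NOB1 fell by 0.72. This call and that of the MYC targets were each lost for at least 1 choice of a left-out NB4 library.

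Several NB4 lists split without a direction of their own. Promyelocyte granule genes had 3 of 12 higher and 7 lower, as over the list alone (adjusted p = 0.16): CTSG and the protease inhibitor CST7 (-1.28) fell while the protease PRTN3 rose by 1.48. Late neutrophil genes had 3 of 7 higher and 2 lower, with 5 and 2 adjusted over the list alone (adjusted p = 0.13), CYBB at 1.07 and NCF4 at -0.76. Stem and progenitor genes had 7 of 16 higher and 6 lower, as over the list alone (adjusted p = 0.83), with GATA2 at 0.83 and HOXA10 at -0.91. DNA replication genes had 6 of 30 higher and 3 lower, with 5 and 3 over the list alone (adjusted p = 0.69), and RRM2, a subunit of ribonucleotide reductase, rose by 0.52. The p53 and cell cycle inhibitor list had 11 of 23 higher and 7 lower, as over the list alone (adjusted p = 0.61), with BTG2 at 1.01 and DDB2 at -0.72; its median (-0.05) and mean (0.05) differed in sign, as they did for the replication (-0.02 and 0.03) and cytokine suppressor lists (-0.04 and 0.02). Apoptosis regulators had 6 of 22 higher and 4 lower, as over the list alone (adjusted p = 0.86), with BIK at -1.48. Suppressors of cytokine signalling had 4 of 12 higher and 4 lower, as over the list alone (adjusted p = 0.99), with SOCS3 at 0.80. Glycolysis and hypoxia genes had 4 of 28 higher and 14 lower, with 5 and 14 over the list alone (adjusted p = 0.12), SLC2A3 at 0.97 and ADM at -1.28. Replication-dependent histones had 5 of 13 higher and 2 lower, as over the list alone (adjusted p = 0.11), with HIST1H4C at 1.01.

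**Figure D2:**
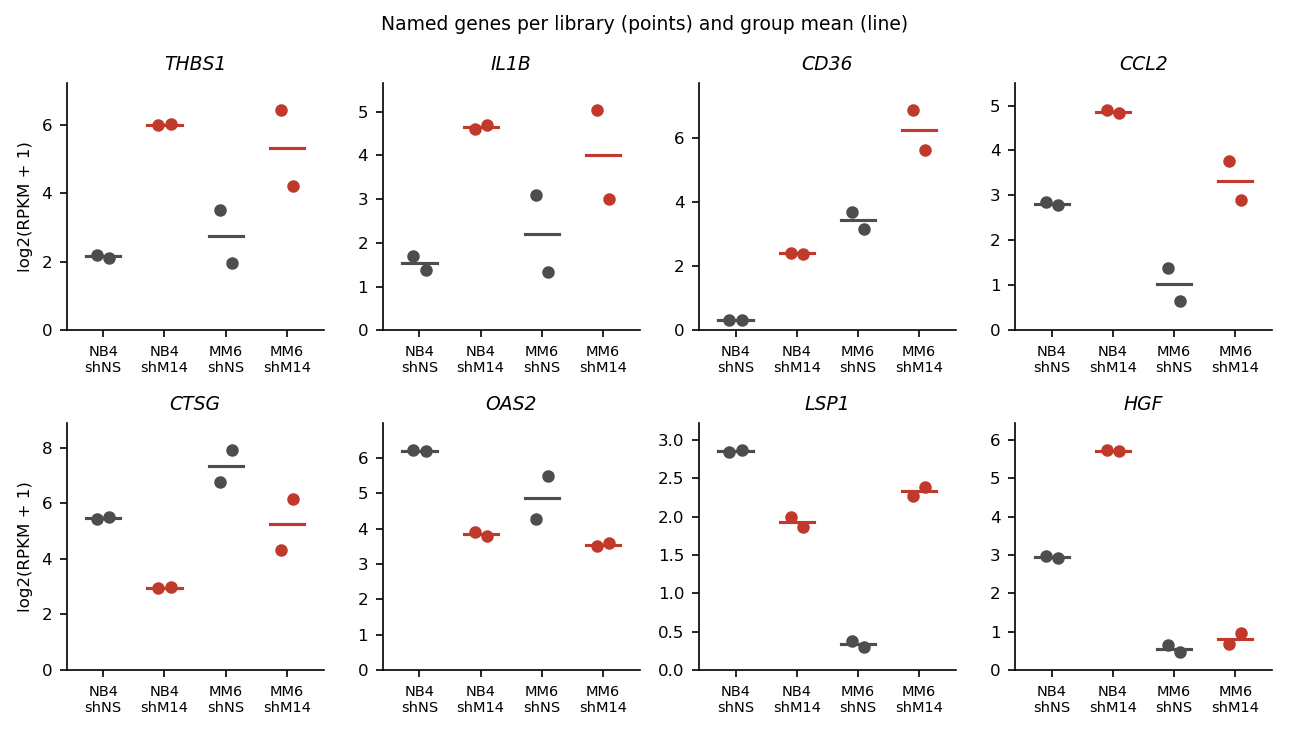
Expression as log2(RPKM + 1) of 8 named genes in the 8 libraries (points, grey for shNS and red for shM14) with the group mean (line), for NB4 and MM6. THBS1 rose by 3.84 and CTSG fell by 2.51 in NB4, and LSP1 had opposite changes in the lines, -0.93 and 2.00.

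In MM6 few genes passed the threshold, and they had varied functions. FN1, which encodes fibronectin, rose from 20.2 ± 3.68 to 102 ± 9.47 RPKM (SD, n = 2 each; 2.30, adjusted p = 0.048). LRRC25, a leucine-rich repeat protein of myeloid cells, rose from 1.36 to 12.3 RPKM (2.48, adjusted p = 0.035). EBI3, a subunit of interleukin 27 (2.11), LSP1, an actin-binding protein of leukocytes (2.00), the caveola protein gene PTRF (1.76) and the adhesion gene AMICA1 (1.60) also rose. The muscle protein gene CSRP3 (-2.76), the prostacyclin synthase PTGIS (-2.27) and INHBA, a subunit of activin (-2.27, from 23.3 to 4.05 RPKM), fell, each with adjusted p = 0.035. These 6 higher and 3 lower genes were all the calls among 11895 tested, each over 2 fold. At an unadjusted p under 0.05 there were 1779 genes, voom on the recovered reads called 39, and the authors' deposited table has 548 genes under the threshold, all 9 included. The MM6 replicates were further apart than those of NB4: the SD of the differences between the control libraries across genes was 0.34 against 0.15. The count depended on the model: median-of-ratios scaling called 3 genes in MM6, the replicate number as a block 1405, and 1 model with all 8 libraries called 1311 in MM6 and 1658 in NB4. That last model uses 1 spread per gene for both lines, so its MM6 count draws on the closer NB4 replicates.

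As groups, several gene lists moved in MM6 although no member passed over all genes. Interferon-response genes were lower in all 38 members by their mean change (median -0.77, adjusted p = 2.4e-11, and 0.72 with an estimated correlation), and 6 fell when adjusted over the list alone. OAS2 had 31.0 and 10.7 RPKM. The size of this shift rested on the controls: the median was -0.38 without control replicate 2 and -1.01 without control replicate 1. Monocyte and macrophage genes had a median of 0.67 over 30 members (adjusted p = 3.4e-08, and 0.58 with an estimated correlation), and 16 rose when adjusted over the list alone. CD14, the lipopolysaccharide co-receptor of monocytes, had 13.4 and 49.8 RPKM, CD36 9.95 and 81.3 RPKM, and CX3CR1 0.295 and 2.89 RPKM. NF-kB and inflammatory genes had a median of 0.58 over 27 members (adjusted p = 1.5e-06, and 0.72 with an estimated correlation), 5 rising over the list alone, with CCL4 at 3.11. Their median was 0.12 without knockdown replicate 1. Late neutrophil genes had a median of 1.10 over 8 members (adjusted p = 6.9e-05, and 0.58 with an estimated correlation), and 4 rose over the list alone, with CHI3L1 at 187 and 778 RPKM. Stem and progenitor genes had a median of -0.40 over 19 members (adjusted p = 4.3e-04, and 0.72 with an estimated correlation), with 1 rising and 7 falling over the list alone. HOXA10, a homeobox gene of progenitors, was at -1.07 and the receptor FLT3 at -0.68.

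Metabolic lists of MM6 also shifted. Cholesterol synthesis genes had a median of -0.52 over 24 members (adjusted p = 4.9e-04, and 0.94 with an estimated correlation); the median was -0.72 and -0.37 in the pairs of same-number libraries, and -0.11 without knockdown replicate 1. Glycolysis and hypoxia genes had a median of 0.21 over 28 (adjusted p = 4.9e-04, and 0.72 with an estimated correlation), with VEGFA at 0.64; without knockdown replicate 2 it was 0.06. Lysosome and autophagy genes had a median of 0.22 over 30 (adjusted p = 7.4e-04, and 0.72 with an estimated correlation); the cathepsin genes CTSZ and CTSB were at 0.65 and 0.69, and NPC1 fell over the list alone (-1.33). Suppressors of cytokine signalling had a median of -0.27 over 12 (adjusted p = 0.013, and 0.72 with an estimated correlation), with 4 falling over the list alone, SOCS1 at -0.88. Oxidative phosphorylation genes had a median of 0.12 over 30 (adjusted p = 0.033, and 0.94 with an estimated correlation). No member of the cholesterol, glycolysis and oxidative phosphorylation lists passed over the list alone. The calls of the lysosome, cytokine suppressor and oxidative phosphorylation lists were each lost for at least 1 choice of a left-out library. The lysosome median was 0.11 without knockdown replicate 1, and that of oxidative phosphorylation 0.04 without control replicate 1.

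The other tested lists were not called in MM6, and no member passed over all genes. Promyelocyte granule genes had adjusted p = 0.33, with 1 rising and 3 falling over the list alone; the protease PRSS57 had 107 and 35.0 RPKM. Immediate early genes had adjusted p = 0.063 and a median of 0.28, and the sign of the median reversed when single libraries were left out. For ribosomal proteins the median was 0.03 (adjusted p = 0.33), although RPLP1 had a change of -0.71. MYC targets (adjusted p = 0.46), ribosome biogenesis (0.44), DNA replication (0.33), mitosis (0.60), p53 targets (0.17), apoptosis regulators (0.60), unfolded protein response (0.60), heat shock (0.70) and histones (0.59) had no member past the list alone. BCL2, which restrains apoptosis, had a change of -1.13, and the median and mean of the mitosis list differed in sign (0.04 and -0.03).

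Changes in the lines resembled each other. Over 10647 genes tested in both, the log2 changes had a Pearson correlation of 0.49 and a Spearman correlation of 0.42 across genes, which are not independent replicates. Of the 4985 of these genes called in NB4, 71.9% had the same sign in MM6. Past the threshold in both were EBI3 (1.72 and 2.11), AMICA1 (0.34 and 1.60) and INHBA (-0.55 and -2.27) with the same sign, against 0.69 and 0.24 genes expected by chance in the directions. LSP1 was called in both with opposite signs. With all 8 libraries in the additive model, 614 genes were higher and 909 lower among 12804; leaving out 1 NB4 library cut these 1523 calls to between 496 and 605, and median-of-ratios scaling gave 877 higher and 938 lower. The rise was led by THBS1 (3.21), the chemokines CCL4 (2.61) and CCL2 (2.18), osteopontin SPP1 (2.50), IL1B (2.46), CD36 (2.44), SGK1 (2.20), C5AR1 (2.18), EBI3 (1.91) and RGL1 (1.68). The fall was led by CTSG (-2.30), IFI27 (-2.10), OAS2 (-1.85), IFI44 (-1.80), LGALS3BP (-1.67), DEFB1 (-1.50), OAS1 (-1.48), PTPN3 (-1.42), MIR3186 (-1.18) and SAMD9L (-1.14). MIR3186 rested on few reads, 38 in controls and 16 with shM14 in NB4 and 11 and 2 in MM6, and did not pass with voom (adjusted p = 0.066). Their adjusted p lay between 9.8e-04 and 0.027.

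**Figure D3:**
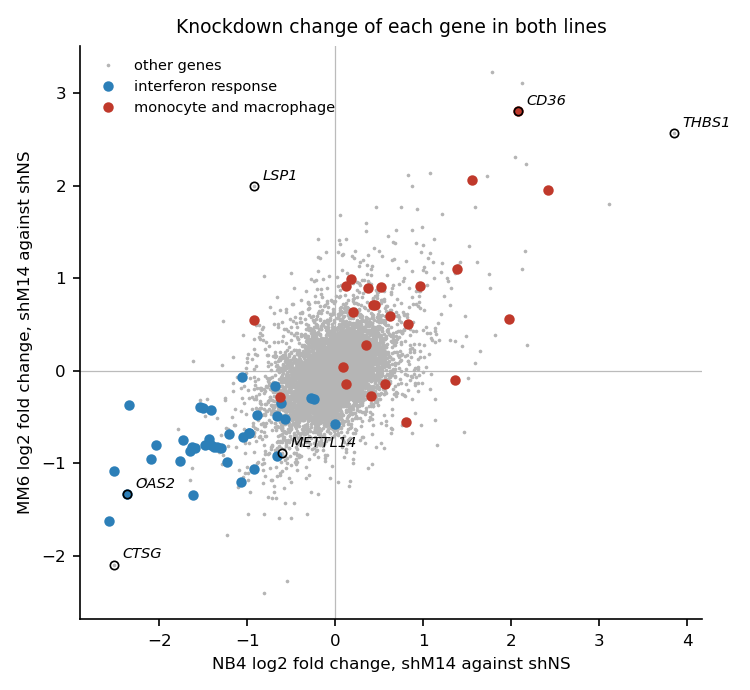
Log2 change of each gene with shM14 against shNS in NB4 (x axis) and MM6 (y axis), with interferon-response genes in blue, monocyte and macrophage genes in red and other genes in grey. The Pearson correlation across the 10647 genes was 0.49, and the interferon medians were -1.36 and -0.77.

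In the fit over both lines the same programmes stood out. Of 38 interferon-response genes 30 fell and 36 over the list alone (median -1.07, adjusted p = 6.4e-19, and 0.41 with an estimated correlation). Monocyte and macrophage genes rose in 13 of 32 and fell in 1, with 14 and 1 over the list alone (median 0.60, adjusted p = 1.3e-08, and 0.15 with an estimated correlation). CD86, a costimulatory molecule, rose by 1.24 and the Fc receptor FCGR2A by 0.67. Inflammatory genes rose in 9 of 28, 12 over the list alone (median 0.62, adjusted p = 6.5e-08, and 0.41 with an estimated correlation), with TNFAIP6 at 1.19 and TNF at 0.91. Oxidative phosphorylation genes rose in 1 of 30, 9 over the list alone (median 0.17, adjusted p = 2.6e-05, and 0.79 with an estimated correlation), and UQCRC2 was at 0.28. Lysosome genes rose in 8 and fell in 3 of 30, 14 and 3 over the list alone (median 0.26, adjusted p = 5.8e-05, and 0.41 with an estimated correlation), with CTSD at 1.15. Ribosomal proteins fell in 2 of 46, 1 over the list alone (median -0.10, adjusted p = 0.011, and 0.80 with an estimated correlation), which reflects NB4 more than MM6 by the difference test; this call held in 4 of 8 fits with 1 library left out, with medians of -0.14 to -0.06. Late neutrophil genes rose in 4 of 9, as over the list alone (median 0.59, adjusted p = 0.014, and 0.41 with an estimated correlation; 0.37 without MM6 control replicate 1, and called in 7 of 8 such fits), with CYBB at 1.17 and CHI3L1 at 1.43. HOXA10 (-0.99), FLT3 (-0.64) and the RNA-binding protein gene MSI2 (-0.52) fell, but the stem and progenitor list was not called (adjusted p = 0.091). The granule genes CST7 (-1.09), CLEC11A (-0.82) and PRSS57 (-1.05) fell along with CTSG. Of the 12 tested members of their list 2 were higher and 5 lower, as over the list alone, and the list was not called (adjusted p = 0.22). TERT fell by 0.65 over both lines.

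**Figure D4:**
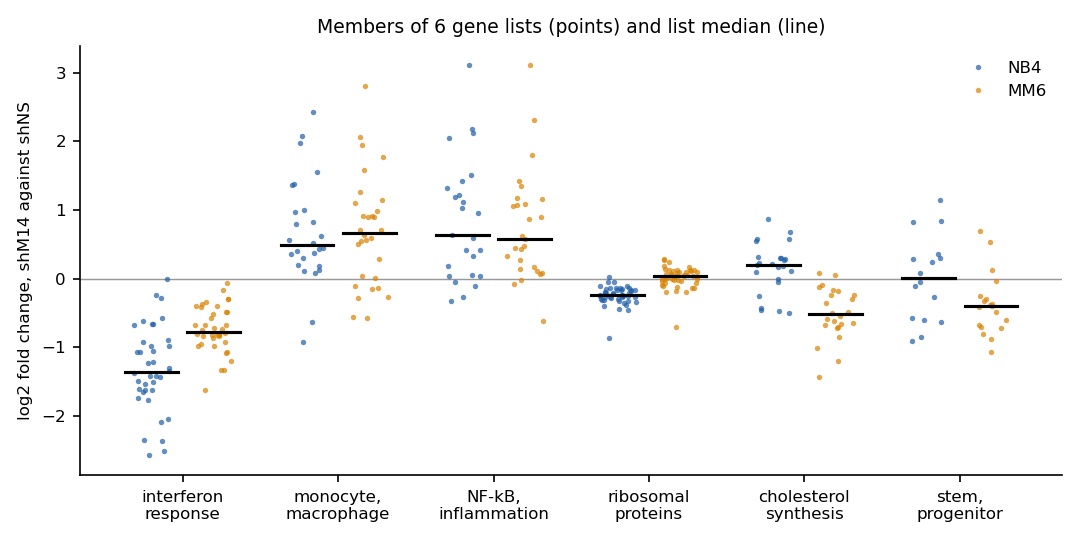
Log2 change with shM14 against shNS of the tested members of 6 gene lists (points) and the list median (line), in NB4 (blue) and MM6 (orange). Interferon medians were -1.36 and -0.77 and monocyte medians 0.49 and 0.67, while cholesterol synthesis went in opposite directions, 0.21 and -0.52.

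The lines differed in their response for 196 genes with a higher and 178 with a lower change in MM6, among 12804. These 374 calls fell to between 5 and 9 when any 1 NB4 library was left out, and rose to 1143 with the replicate number as a block. LSP1 differed most by p: it fell from 6.25 to 2.82 RPKM in NB4 and rose from 0.260 to 4.03 RPKM in MM6 (difference 2.92, adjusted p = 0.0011). SEMA4A, a semaphorin, fell by 0.81 in NB4 and was at 1.03 in MM6 (difference 1.84, adjusted p = 0.0023). Other differences reflected a gene expressed in 1 line. H19 (difference 1.92), the nucleotidyltransferase gene FAM46C (1.72) and CHAT (1.58), which encodes choline acetyltransferase, fell in NB4 and were under 0.1 RPKM or listed at 0 in MM6. HGF (-2.50) and RAB27B (-1.40), a vesicle GTPase, rose in NB4 and had under 1 RPKM in MM6. CSRP3 (-2.72) and PTGIS (-2.21) fell in MM6 and were under 1 RPKM in NB4. SNORD116-28 (-1.34) rested on few reads, 12 in controls and 2 with shM14 in MM6, and did not pass in MM6 alone (adjusted p = 0.060). Among lists, cholesterol synthesis had lower changes in MM6 than in NB4 (median difference -0.66, adjusted p = 1.9e-04, and 0.74 with an estimated correlation), between -1.02 and -0.31 with 1 library left out. Ribosomal proteins (0.24, adjusted p = 2.5e-10, and 0.36 with an estimated correlation) and interferon genes (0.55, adjusted p = 2.9e-06, and 0.71 with an estimated correlation) had higher changes in MM6, where their medians were 0.03 and -0.77; the interferon difference was 0.20 without MM6 control replicate 1 and 0.88 without control replicate 2. Glycolysis genes did too (0.32, adjusted p = 6.1e-05, and 0.36 with an estimated correlation), between 0.18 and 0.46 with 1 library left out. Unfolded protein response (-0.24, adjusted p = 6.1e-05), stem and progenitor (-0.21, adjusted p = 0.012) and heat shock genes (-0.24, adjusted p = 0.047) had lower changes in MM6; with an estimated correlation their adjusted p was 0.36, 0.36 and 0.71. The heat shock call held in 4 of 8 fits with 1 library left out, with a median of -0.08 without MM6 knockdown replicate 1, and the stem and progenitor call in 7 of 8; the unfolded protein response median was between -0.38 and -0.21.

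Markers of other cell types were few among the tested genes. Of the erythroid markers 1 was tested, EPOR at -0.03 in NB4 and 0.01 in MM6. The megakaryocyte list had THBS1 up, ITGA2B (-1.13) down and NFE2 (0.47) up in NB4, and in MM6 none of 4 passed. B cell markers had 0 of 2 members past the threshold in each line, CD79B at -0.12 and -0.43. T and NK cell markers had 2 of 4 higher and 2 lower in NB4 (NKG7 at 0.84, NCAM1 at -0.48) and 0 of 2 in MM6. Dendritic and mast cell markers had EPX (1.27), HDC (0.92) and TPSB2 (0.30) higher in NB4 and 0 of 3 past the threshold in MM6, where all 3 were lower by their mean change, 2 of them over the list alone, with TPSAB1 at -0.64. Their changes differed between lines (median difference -0.94 over 5 members, adjusted p = 1.9e-04, and 0.36 with an estimated correlation). Only 3 members were tested in each line alone. HDC, whose difference of -0.94 is the median, and EPX (-1.18) had a mean under 1 RPKM in both MM6 groups. For these genes the difference reflects expression in NB4 and little room to change in MM6. Epithelial, fibroblast and endothelial markers had 2 of 5 higher and 2 lower in NB4 (adjusted p = 0.87), with PECAM1 at 0.55 and KRT18 at -0.39, and 0 of 4 past the threshold in MM6. Median and mean of these last markers differed in sign in NB4 (-0.02 and 0.01) and MM6 (-0.03 and 0.05). None of the 13 mitochondrially encoded genes was among the genes listed. None of the list calls in any of the 4 comparisons held with an estimated correlation. The smallest adjusted p there were 0.21, 0.58, 0.15 and 0.36 in NB4, MM6, both lines and the difference. That setting also lowers the degrees of freedom of the test, so these losses do not measure correlation alone. In NB4 the camera p of the monocyte list went from 2.6e-08 to 0.025, although its estimated correlation was only -0.012.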

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

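The tests of the interferon, replicate, MYC target and scaling explanations below were chosen only after the results were seen. Those of other groupings of the libraries, of gene length, length and expression of ribosomal protein mRNAs, and the correlation without 3 lists were set down before their values were computed; the demand for a close match to the ribosomal mRNAs was added after.

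The response differed between the lines for 196 genes with a higher and 178 with a lower change in MM6, but leaving out any 1 NB4 library cut the 374 calls to between 5 and 9, and the replicate block raised them to 1143. Some of these genes had a mean under 1 RPKM in both groups of 1 line, where log2(RPKM + 1) leaves them little room to change. In MM6 these were H19 (1.92), FAM46C (1.72), CHAT (1.58), ITGA2B (1.02), CDKN1C (0.96), HGF (-2.50), RAB27B (-1.40), EPX (-1.18), ANGPT1 (-1.08), HDC (-0.94) and MMP9 (-0.90). In NB4 they were FN1 (2.30), LRRC25 (2.15), CX3CR1 (1.72), PTRF (1.49), CSRP3 (-2.72), PTGIS (-2.21), EGFL7 (-0.82) and SNORD116-28 (-1.34), the last with 0 reads in NB4 and only 12 in controls and 2 with shM14 in MM6. Other named genes with a higher change in MM6 than in NB4 were LSP1 (2.92), SEMA4A (1.84), AMICA1 (1.26), BIK (1.0), NCF4 (0.93), VEGFA (0.83) and IER5 (0.81). The interferon genes OAS3 (1.97) and IFIT2 (1.23) were reduced more in NB4. Other named genes with a lower change in MM6 were IKZF2 (-1.95), ICAM1 (-1.91), INHBA (-1.71), NPC1 (-1.13), PRTN3 (-1.11), PRSS57 (-1.09), SOCS1 (-1.0), NKG7 (-0.94), PDIA4 (-0.92), DDIT4 (-0.91), CHST2 (-0.87), LAMP1 (-0.69), DNAJB9 (-0.64) and XBP1 (-0.61). The sign for OLIG1 (-1.02) on the scale with 1 RPKM added is not that of the ratio: in the authors' deposited table its log2 fold change was 2.31 in NB4 and 3.72 in MM6, a larger rise in MM6. As lists, ribosomal proteins (0.24), interferon (0.55) and glycolysis genes (0.32) were higher by median difference, and stem and progenitor (-0.21), unfolded protein response (-0.24), heat shock (-0.24), cholesterol synthesis (-0.66) and dendritic and mast cell genes (-0.94) lower. With an estimated correlation none of these lists was called (smallest adjusted p = 0.36). The dendritic and mast cell list included HDC and EPX, named above as under 1 RPKM in MM6. For the effect common to both lines, 1 of 34 usable splits called as many genes, the real one with 1523, and the highest other called 6. The other splits mix or swap knockdown and control libraries in at least 1 line. A knockdown effect then enters their spread and lowers their counts, so this comparison cannot exclude chance.

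Interferon-response genes fell in NB4 and as a list in MM6, though with an estimated correlation the list was called in neither (adjusted p = 0.21 and 0.72). The choice of scaling hardly mattered, since the MM6 median stayed at -0.73 with median-of-ratios scaling. That scaling moved the MM6 changes by a median of only 0.04, so this test could hardly have come out otherwise. The median change over all tested MM6 genes was -0.03, so the list fell relative to other genes. A change in total RNA per cell would not be seen with either scaling. A fall in a single MM6 replicate stayed open, because 31 of 38 members were lower in the replicate with the smaller change, between the bounds of 25 and 33 that had been set. In MM6 the controls themselves differed, with an interferon median of -0.68 between control replicates 1 and 2 against 0.17 between the knockdowns. A response to hairpin vectors could not be tested against cells without a hairpin, which gave 0 libraries. Both groups carried a hairpin, so a response shared by them would cancel in shM14 minus shNS. A response particular to shM14 or to shNS could not be told apart from loss of METTL14, because each was the only hairpin of its kind.

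The MM6 replicates differed more than those of NB4. This pattern had first been put as a difference along the direction of the knockdown; those first tests were weak (Pearson 0.15 and Spearman 0.10 with the NB4 change across 10647 genes, 0.16 in the more abundant ones, and 7 of 10 called lists larger in replicate 1), and it was then reworded. Swapped labels were excluded (METTL14 stayed 5.97 RPKM apart), as was read depth, since among the most abundant genes the SD ratio of MM6 over NB4 controls was 3.01. A stronger knockdown in 1 replicate could not be the whole cause, because the controls alone had an SD ratio of 2.30. That ratio does not exclude an added difference between the knockdown libraries. The METTL14 change in MM6 was -0.884 without knockdown replicate 1 and -0.885 without knockdown replicate 2. These values argue against an unequal lowering of METTL14 mRNA in the MM6 knockdown libraries. A condition shared by the libraries of the same number was not excluded, with a correlation across genes of 0.69 in MM6 against 0.10 in NB4. This test cannot decide it. Each group gave only 1 difference, and unrelated variation in the same genes could give such a correlation under arbitrary numbering. The interferon list did not follow a shared shift, with medians of -0.68 between the MM6 controls and 0.17 between the knockdowns.

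Ribosomal protein mRNAs fell as a list in NB4 and not in MM6, though the NB4 call was lost with an estimated correlation (adjusted p = 0.36). Length and expression level stayed open as a cause: the genes nearest in both had a median NB4 change of 0.13, but the match was poor, with a median length of 1843 against 870 and a median RPKM of 591 against 1283. The choice of scaling hardly mattered, with a median of -0.20 under median-of-ratios scaling. That scaling moved the NB4 changes by a median of only 0.03, so this test could hardly have come out otherwise. The median change over all tested NB4 genes was -0.01, so these mRNAs fell relative to other genes.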

How the results depend on the processing

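Alternatives added only after the results were seen were the models with all 8 libraries, the variance trend, voom and median-of-ratios scaling. Fitting all 8 libraries together had been planned for counts, but not for RPKM values. METTL14 in MM6 passed with the replicate number as a block (-0.88, adjusted p = 0.0089) and with all 8 libraries in 1 model (-0.88, adjusted p = 0.0032). It also passed with voom on all 8 (-0.98, adjusted p = 0.0026) and with all 8 and the block (-0.88, adjusted p = 0.0043). The models with all 8 libraries use 1 spread per gene for both lines. The SE of METTL14 in MM6 was 0.085 in that model, against 0.13 in MM6 alone. The control replicates differed more in MM6 (SD 0.34) than in NB4 (0.15), so these models may call too many genes in MM6. Leaving 1 library out gave METTL14 changes of -0.93 to -0.84 in MM6, and -0.69 to -0.53 in NB4. The 5460 genes of NB4 became 1658 with all 8 libraries, 1841 with voom on all 8 and 3120 with all 8 and the block, and 3049 to 4637 with 1 library left out, lowest without knockdown replicate 1 (3049) or 2 (3260). The 9 genes of MM6 became 0 without a filter, 47 at 10 CPM, 1405 with the block, 1311 with all 8, 39 with voom, 1442 with voom on all 8, 3 with median-of-ratios scaling and 2752 with all 8 and the block. Leaving 1 MM6 library out gave 5 to 23 (5 without knockdown replicate 1, 14 without knockdown replicate 2, 23 without control replicate 1). The common count of 1523 became 2144 with voom on the recovered reads. With 1 library left out it ranged from 496 to 1926, with 521, 605, 496 and 521 without each NB4 library. The 374 genes differing between lines became 203 with a pseudocount of 0.1, 1143 with the block and 207 with voom; leaving 1 out gave 5 to 742, with 6, 5, 8 and 9 without each NB4 library, 189 without MM6 control replicate 1 and 742 without MM6 knockdown replicate 2. The 3 genes called the same way in both lines became 0 without a filter, 20 at 10 CPM, 678 with the block, 399 with all 8, 21 with voom, 474 with voom on all 8, 0 with median-of-ratios scaling and 955 with all 8 and the block, and 2 to 12 with 1 library left out (12 without MM6 control replicate 1, 8 without MM6 knockdown replicate 2). Called lists were 0 in NB4 and 0 in MM6 with an estimated correlation, and 11 to 14 and 11 to 12 with 1 library left out. Reversed in sign were immediate early genes of MM6, -0.75 without control replicate 2 and -0.49 without knockdown replicate 1 (range -0.75 to 1.43), and histones of MM6, -0.31 without knockdown replicate 1 (to 0.47). In the difference, without MM6 knockdown replicate 1, inflammatory genes reversed at -0.37 (to 0.45) and immediate early genes at -0.82 (range -1.05 to 1.07). The cause of these shifts was not tested. The planned count models and their filters were not run, and neither was a stricter threshold on the authors' adjusted p. Voom and the filter of 10 CPM used the recovered reads. Same-number libraries deviated together in MM6 (0.70) and not in NB4 (0.08), but the labels do not state a pairing, so the block results stay conditional. Depth limits low-abundance genes most.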

Other observations

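Tests named here were chosen only after the results were seen, except those of gene length and of the correlation without 3 lists. With METTL14 lowered, the fit over both lines had more monocyte, inflammatory and lysosome transcripts and fewer interferon-response transcripts at the preset correlation, and the promyelocyte protease gene CTSG fell. With an estimated correlation none of these lists was called (adjusted p = 0.15, 0.41, 0.41 and 0.41). The likeness of the lines was not carried by the listed interferon, monocyte and inflammatory genes alone. Without those 3 lists the Pearson correlation was still 0.46, over 10561 of the 10647 genes. Few genes were removed, and genes of the same programmes outside the lists stayed in. The test therefore cannot decide whether the wider programmes carry the likeness. CD36, CD86, CCL2, SPP1 and C5AR1 rose, but whether this is monocytic maturation stays open: of the stem and progenitor genes HOXA10 and FLT3 fell while GATA2 and LMO2 rose, and that list was not called (adjusted p = 0.091). MYC fell in NB4 while its targets as a set did not follow, with a list median of 0.13.

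One explanation is that less m6A stabilises or destabilises transcripts directly. Because m6A sits mainly in long internal exons and near stop codons, loss from long transcripts could shift changes with length, but the Spearman correlation of change with length across genes was -0.0574 in NB4, which excludes an increase with length by the bounds set. Methylation was not measured in these libraries, so direct and indirect effects could be separated by m6A maps and RNA half-lives in the same cells. A loss of tonic interferon signalling could explain the interferon fall; the MM6 median was -0.73 under median-of-ratios scaling, and blocking the receptor in control cells would test it. A response particular to shM14 or to shNS may contribute, as each was the only hairpin of its kind and 0 libraries came from cells without a hairpin. A further hairpin and re-expression of METTL14 would test this.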
